A study of Drosophila melanogaster with 3 samples.

How the data were processed

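Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos of both sexes, collected 0 to 16 h after egg laying, from a transgenic line whose CG5180 protein carries a green fluorescent protein (eGFP) tag, per the labels. The antibody recognised GFP, and chromatin was sheared by sonication to a stated size range of 200 to 800 bp, per the labels. The series holds 1 group of 3 biological replicates, numbered as in the labels. No group without the tag and no control library was analysed here.

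The authors deposited 5 peak lists for each of the genome builds dm6 and dm3, 10 in all. Per the README notes deposited with each library, each replicate's list was derived from that replicate's alignments and 1 further file, the pooled list from the alignments of the 3 replicates and the same file, and the IDR list from the replicate lists and the pooled list. The further file is taken here to be the control, since the notes also derive the control-normalised signal from it. IDR, the irreproducible discovery rate, is a method that keeps peaks ranked alike in several lists. The aligner, the peak caller, the IDR threshold and their versions are not given in the sources used here. The signal value of each peak is a score that the authors' caller assigned, without a fixed range, and the deposited lists give a −log10 q-value beside it. Both were used only to describe and rank peaks within a list, because neither was scaled between lists. The number of reads behind a list is unknown, so precision is given as counts of peaks or genes, with Wilson 95% intervals, and a count of 0 is given the upper limit that 3 counts would allow. Intervals and limits cover counting error only.

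Coordinates are 1-based and on dm6. The chromosome sequences of genome release 6 and the gene models of Ensembl release 115 were used, and every peak of the 5 dm6 lists lay within the reference chromosomes. The dm3 lists were used only for counts, widths and shares, since positions were not converted between builds. Peaks, genes and transcription start sites (TSSs) were taken on the arms 2L, 2R, 3L, 3R, 4 and X, which hold 13945 protein-coding genes.

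A replicate recovered an IDR peak when a summit of its 5400 strongest peaks lay within 200 bp of the IDR summit, and 100 draws of random positions on the same chromosomes gave the background. A promoter peak had its summit within 250 bp of a protein-coding TSS. Other summits were assigned in the order 5' UTR, 3' UTR, coding sequence, other exon, intron and intergenic. IDR peaks were set against the 22938 peaks of the pooled list that overlap no IDR peak. A gene was bound when an IDR summit lay within 250 bp of any of its TSSs. Membership of 27 gene lists was compared with all other protein-coding genes, or with all genes for tRNAs and small nuclear RNAs. Of 219 members given by symbol, 209 were found, and the other lists were patterns of gene symbols. The pattern for chorion genes also took in Cp190, an insulator protein. The motifs were 18 consensus sequences, sought on both strands within 100 bp of the summit and in a window of equal width 500 bp to a randomly chosen side, and within 250 bp of the TSS of bound and unbound genes. All 8-mers were ranked on odd-numbered peaks in order of signal, and the 20 with the largest excess were tested on even-numbered peaks.

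Fisher's exact test was used for shares of different peaks or genes, and the exact McNemar test for a peak and its own flank, both two-sided. Log2 ratios have 0.5 added to each count only where a count is 0. Benjamini-Hochberg (BH) adjustment was made within each family, of 7 features, 6 arms, 27 gene lists, 18 motifs or 20 8-mers, and the threshold was 0.05. Since there is 1 group, no test compares samples. The tests compare peaks or genes within pooled data, and peaks and genes are not replicates. The spread between replicates is given as the SD over the 3 replicates' 5400 strongest peaks.

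Gene lists, motifs, main tests and the rule for named genes were fixed before the data were examined. The rule names CG5180, the gene of the nearest protein-coding TSS for the 25 strongest IDR peaks found in all 3 replicate lists, and up to 4 bound members per gene list with the largest signal value. Genes outside it are said to have been chosen after their values were seen. The alternatives were other windows, TSS sets, overlap rules, backgrounds and peak sets, a stricter peak threshold, and leaving out each replicate. Added after the data were seen were the strongest of overlapping peaks, genes matched on the number of TSSs by 10000 random draws, and the alternatives for 8-mers. For the IDR list, leaving out a replicate kept peaks found among the strongest of both other replicates.

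On simulated data, planted promoter peaks were recovered within 0.0183 percentage points among 5400 peaks. For the gene list test on 13945 genes, 96.7% of planted lists bound at 50% were called, and 0.417% of the others. The planted lists had 86, 48 and 23 members, so smaller lists are not covered. All other genes were bound at a common rate whatever their number of TSSs. The simulation therefore does not show how often lists would be called because their genes differ in TSS number. A planted 8-mer was called in 100% of 3 simulated sets of 5400 peaks, while 0 of 60 8-mers and 0 of 54 motif tests passed at random positions. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.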

Results

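The series mapped embryonic chromatin precipitated with tagged CG5180 protein. No control or other GFP line was analysed here, so regions enriched in any GFP ChIP cannot be excluded, and bound means only that an IDR summit lies at a TSS. CG5180 is a Drosophila gene still known by its annotation number, and its product was tagged with eGFP and precipitated with an antibody against GFP. The 3 biological replicates of whole embryos aged 0 to 16 h form a single group. Each replicate list and the pooled list hold 30000 peaks on dm6, so list length says nothing of signal. The IDR list holds 5400 peaks with a median width of 464 bp, which cover 2.26 Mb in 4799 separate regions. All 5400 were the strongest 5400 peaks of the pooled list. On dm3 the IDR list holds 4931 peaks, again exactly the strongest 4931 of its pooled list, with 17.99% on the X chromosome against 17.9% on dm6. Read depth is unknown, and signal values are the authors' own and comparable only within a list.

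The 25 strongest peaks with a summit in all 3 replicate lists lay at or near genes of varied function. Peaks at sgl, which encodes the UDP-glucose dehydrogenase needed to make heparan sulfate, and at Egfr, the epidermal growth factor receptor, had signal values of 49261 and 46620. The Egfr peak (2R, 21521586 to 21522954) has its summit 146 bp from a TSS. Also among the 25 strongest were peaks at rho, whose protease releases ligands of that receptor (signal value 22352), at mew, an integrin subunit (40154), and near pyr, which encodes a ligand of the FGF receptor Heartless (31602, 1910 bp from the TSS). Transcription factor genes in the set were net (40750), vri (24672) and chn (25424, 5684 bp from its nearest TSS). The peak at Axn, a scaffold protein that restrains Wnt signalling, is shared with the ribosomal protein gene RpS28a (23117, 3R, 30022166 to 30023475).

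The strongest peak of all had a signal value of 50504 and was intergenic (2R, 16827974 to 16831257), 2040 bp from the nearest TSS, that of CG34460. The peak of rank 4, with a signal value of 44509, lay 10270 bp from the nearest TSS, that of CG15725 (X, 12715403 to 12717375), in an intron of the corepressor gene Smr, which was named after its value was seen. Further promoter peaks in the set were those at CG13921, kek5, CG14441, cv-c, SKIP, fend, CG31688, CG1607, Pgant9, Doa, CG42394 and KCNQ, with signal values from 22275 at KCNQ to 35820 at CG13921. Peaks at REG and CG3655 had their summits 1992 and 298 bp from a TSS. In all, 19 of the 25 summits were within 250 bp of a TSS. None of the 25 ranked below position 31 in any replicate list.

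Replicates recovered most IDR peaks. Among its own 5400 strongest peaks, replicate 1 held 87.6% of the IDR peaks, replicate 2 held 86.0% and replicate 3 held 83.9%, a mean of 85.8% ± 1.88 (SD, n = 3). Random positions gave 1.54%, and at most 1.98% in any of 100 draws. The 3 replicates shared 3709 IDR peaks (68.7%) among their strongest. In the whole lists the mean recovery was 99.1% ± 0.0932. The replicate lists enter the making of the IDR list, so recovery above random positions was built in, for the strongest peaks too. Replicates were also compared with each other. Of the strongest 5400 peaks of replicate 1, 79.1% lay within 200 bp of one of those of replicate 2, and 78.0% of replicate 3. For replicate 2 against replicate 3 the share was 78.4%. Across matched IDR peaks, Spearman's rho of signal values between replicates was 0.804, 0.797 and 0.793, and these are correlations across peaks, which are not independent replicates.

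IDR peaks were found at promoters more often than weaker peaks, and the shares of introns, intergenic sequence and coding sequence were lower. Each summit was assigned to the first feature that applied, so a larger promoter share by itself lowers the other shares. Summits outside promoters were not tested on their own. Of 5400 IDR summits 1676 were at promoters and 2332 in introns, against 2792 and 11846 of 22938 non-IDR summits. Among summits outside promoters, introns thus held a larger share of IDR than of non-IDR summits. The lower intron share over all summits is therefore no sign of avoidance, and the lower intergenic share is not separate evidence of it. Of the 5400 IDR peaks, 1676 had a summit within 250 bp of a protein-coding TSS (31.04%, Wilson 95% interval 29.8 to 32.3), against 2792 of 22938 non-IDR peaks (12.2%, 11.8 to 12.6). The odds ratio was 3.25 (Fisher's exact test, two-sided, p = 1.21e-223). The replicates' strongest peaks gave 31.9% ± 1.87 (SD, n = 3). Random positions gave 6.43%. Introns held 43.2% of IDR and 51.6% of non-IDR summits (exact BH p = 1.05e-28), and intergenic sequence 18.7% and 25.2% (BH p = 2.00e-24). Coding sequence held 1.11% and 4.02% (exact BH p = 1.11e-31), and 3' UTRs 1.17% and 2.68% (BH p = 2.67e-12). Shares in 5' UTRs (1.91% and 1.84%, exact BH p = 0.737) and other exons (2.85% and 2.41%, BH p = 0.0759) did not pass the threshold.

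The promoter share rose with peak strength. It was 49.4% in the strongest 540 IDR peaks (45.2 to 53.7) and 25.7% in the weakest 540 (22.2 to 29.6), an odds ratio of 2.82 (Fisher's exact test, two-sided, p = 9.84e-16). The replicates' own strongest 540 peaks gave 48.0% ± 0.214 and their weakest 540 of 5400 gave 25.2% ± 3.80 (SD, n = 3).

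**Figure D1:**
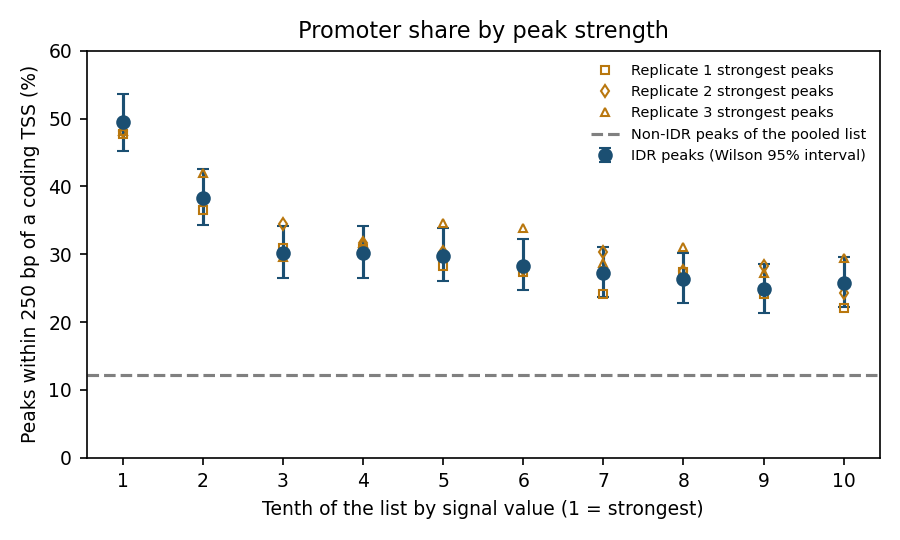
Share of peaks with a summit within 250 bp of a protein-coding TSS (vertical axis, percent) in 10 equal groups of the list by signal value (horizontal axis, 1 the strongest). Filled circles are IDR peaks with Wilson 95% intervals, open symbols the 3 replicates' strongest 5400 peaks, and the dashed line the non-IDR peaks at 12.2%; the IDR share is 49.4% in the strongest group and 25.7% in the weakest.

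Genes for cytosolic ribosomal proteins were bound far more often than other protein-coding genes. Of 13945 protein-coding genes, 1675 (12.01%) had an IDR summit at a TSS, and 1733 ± 151 (SD, n = 3) in the replicates' strongest peaks. Among cytosolic ribosomal protein genes 57 of 86 were bound (66.3%, Wilson 95% interval 55.8 to 75.4), an odds ratio of 14.9 (Fisher's exact test, BH p = 7.90e-31), and 57.3 ± 4.04 in the replicates. The strongest were RpS28a, RpS27 (signal value 1146), RpL7 (1012) and RpS10b (782), of which RpS27 and RpL7 share their peaks with Nup37 and Ripalpha. Mitochondrial ribosomal protein genes did not share this excess, with 7 of 73 bound (exact BH p = 0.852), among them mRpL41 (2248) and mRpS10 (2038, shared with Art3), though the difference between the lists was not tested.

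Of the patterning lists, the dorsoventral, Hox and segment polarity genes were bound more often than other genes in the main analysis, while gap and pair-rule genes did not pass. The dorsoventral list had 9 of 23 bound (39.1%, 22.2 to 59.2, odds ratio 4.73, exact BH p = 0.00387), and its strongest were rho, pyr, the GATA cofactor gene ush (1240) and SoxN (1132). The pyr peak counted here (18650) has its summit at a TSS and is not the stronger peak 1910 bp away. Of the Hox genes, which set segment identity, 4 of 8 were bound (odds ratio 7.34, exact BH p = 0.0328), namely Dfd (2695), lab (806), Abd-B (623) and Ubx (383). Segment polarity, Wnt and Hedgehog genes had 6 of 17 bound (odds ratio 4.01, exact BH p = 0.0341), led by Axn, the Wnt co-receptor gene arr (1446), nkd (409) and hh (337). In contrast 0 of 8 pair-rule genes were bound, which allows a share of up to 37.5%, and this did not pass the threshold (exact BH p = 0.820). Replicates gave 9.67 ± 0.577 dorsoventral, 4 ± 0 Hox and 6.67 ± 0.577 segment polarity genes (SD, n = 3).

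These patterning calls depended on the background. Against only the genes with any pooled peak at a TSS, odds ratios were 1.35 for the dorsoventral list (exact BH p = 0.941), 5.41 for Hox genes (BH p = 0.739) and 1.62 for the segment polarity list (BH p = 0.885), while ribosomal protein genes had 7.93 (BH p = 1.52e-11). The dorsoventral and segment polarity odds ratios had been 4.73 and 4.01 against all other genes. That of the Hox genes, 7.34 before, fell less, and fewer genes were compared, so the missed threshold does not show that their excess was gone. In place of Fisher's exact test, 10000 random draws of genes with the same number of TSSs were added after the data were seen, and observed over expected was 2.11 for the dorsoventral, 2.39 for the Hox and 2.28 for the segment polarity list (BH p = 0.0990, 0.266 and 0.194) and 4.20 for ribosomal protein genes (BH p = 0.00270). Hox and segment polarity genes did not pass within 500 bp of a TSS (odds ratios 5.63 and 3.07, exact BH p = 0.0588 and 0.0802) or within 1000 bp (4.53 and 2.47, BH p = 0.121 and 0.217). The segment polarity list also missed the threshold in the stronger 2700 peaks (3.97, exact BH p = 0.0812) and with the peak interval over the TSS (3.51, BH p = 0.0840), with odds ratios near the 4.01 above.

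Chemoreceptor, cuticle, histone, oxidative phosphorylation and tRNA genes were bound less often than other genes. None of 179 chemoreceptor genes was bound (upper limit 1.68%, exact BH p = 2.08e-09), and 1 of 121 cuticle protein genes was, Cpr76Bc (BH p = 4.62e-05). Of 111 replication-dependent histone genes 0 were bound (upper limit 2.70%, exact BH p = 9.76e-06), but these are near-identical copies where reads can be hard to place. Oxidative phosphorylation genes had 3 of 90 bound (ND-51, ATPsynCF6 and SdhC, exact BH p = 0.0316), and tRNA genes 11 of 295 (BH p = 3.07e-04), one of them, tRNA:Cys-GCA-1-3, under a peak of signal value 19296. The peaks at ND-51, ATPsynCF6 and SdhC are shared with CG13994, Sec13 and Tctp. With genes that have a pooled peak as background, chemoreceptor, cuticle and oxidative phosphorylation genes no longer passed (exact BH p = 0.271, 0.791 and 0.0659), though their odds ratios of 0, 0.224 and 0.223 stayed low beside 0, 0.0605 and 0.251 against all other genes. Within 1000 bp, oxidative phosphorylation and tRNA genes did not pass (exact BH p = 0.143 and 0.187), and the odds ratio of oxidative phosphorylation genes moved from 0.251 to 0.501. Oxidative phosphorylation genes also missed the threshold with the peak interval over the TSS (exact BH p = 0.0799), though their odds ratio there, 0.289, changed little. With random draws matched on the number of TSSs in place of Fisher's exact test, tRNA genes did not pass (BH p = 0.194). Observed over expected was then 0.587, where the odds ratio against all other genes had been 0.339.

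The other lists did not pass the threshold in the main analysis. Among regulators, 6 of 24 Polycomb and trithorax group genes were bound, brm (889), Trl (521) and E(z) (514) among them, and 4 of 14 insulator genes, Chro (1851), Cp190 (1016), Dref (715, shared with RpL13) and Trl. The peaks at brm, E(z), Chro and Cp190 are shared with Arl1, Cnep1r2, Ssl1 and CG4338. The proneural and Notch list had 6 of 24, led by pros (2511) and mam (1824), the gap and head list 3 of 12 (cad, oc and kni), and the mesoderm and muscle list 4 of 21, led by sns (2347) and tin (649). Housekeeping lists gave 4 of 25 for the spliceosome, with Sf3b1 at 16457 (shared with Nle), 4 of 44 for translation initiation factors, with eIF4A at 1570, and 4 of 33 for aminoacyl-tRNA synthetases. General transcription and Mediator genes gave 5 of 63, proteasome subunits 1 of 48 (Rpn8), cell cycle and replication genes 4 of 33, with Orc4 at 492, and autophagy genes 3 of 20. Heat shock and chaperone genes gave 6 of 37, with Hsp83 at 1290 and Hsp27 at 900, small nuclear RNAs 3 of 32 and gut serine proteases 1 of 26. The only bound member of the 16 chorion and vitelline membrane symbols was Cp190, an insulator protein that the symbol pattern also takes in, and the other 15 had none. Exact BH p ranged over these lists from 0.0696 for proteasome subunits to 1. Some passed under other settings: the proneural and Notch list within 100, 500 and 1000 bp of a TSS (odds ratios 3.77, 4.03 and 3.84, exact BH p = 0.0483, 0.00595 and 0.00880, against 2.45 and 0.134 within 250 bp), proteasome subunits, which were bound less often, within 500 bp (0.119, BH p = 0.0218), and insulator genes in the stronger 2700 peaks (5.16, BH p = 0.0451).

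**Figure D2:**
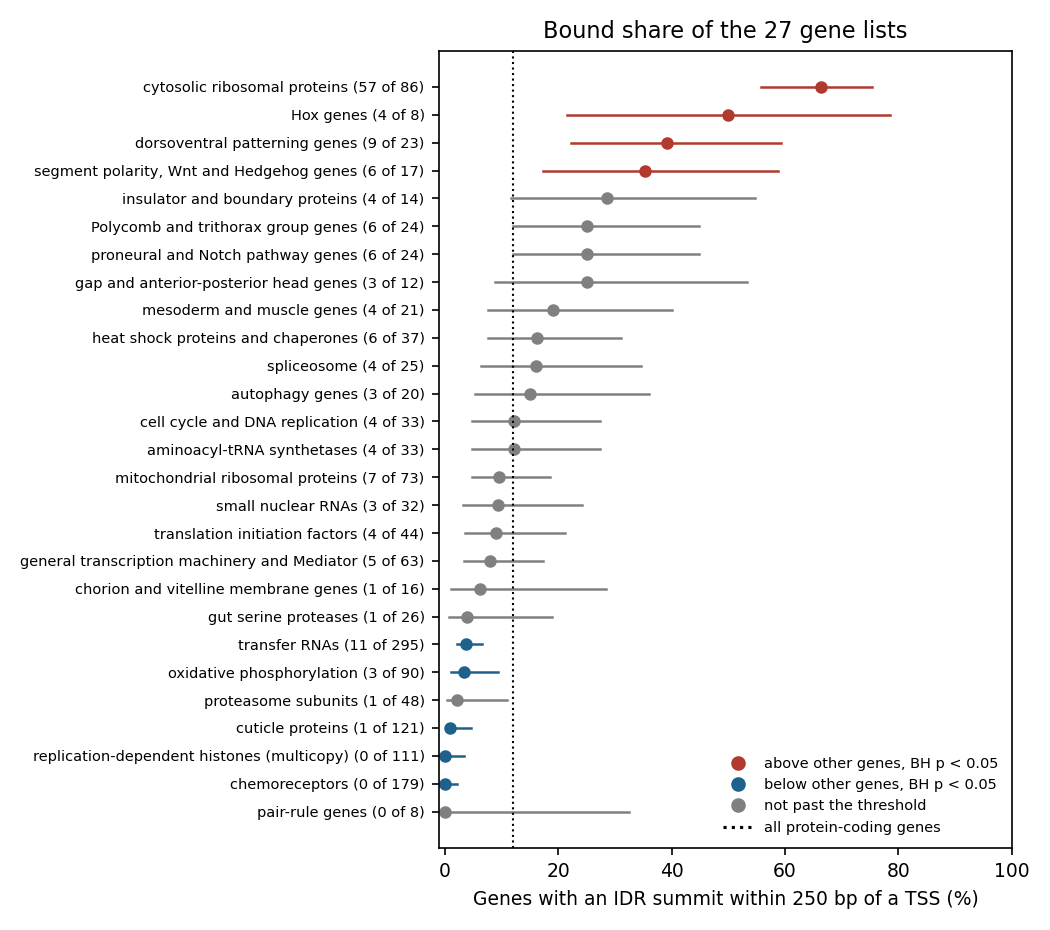
Share of each list's genes with an IDR summit within 250 bp of a TSS (horizontal axis, percent), with Wilson 95% intervals; numbers beside the names are bound genes and members. Red lists lie above and blue lists below other genes at a BH p under 0.05 (Fisher's exact test over 27 lists), grey lists did not pass, and the dotted line marks the 12.01% of all protein-coding genes; cytosolic ribosomal proteins reach 66.3%.

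Bound promoters were rich in GAGA elements. The GAGA factor sequence GAGAGAG lay within 250 bp of the TSS in 16.4% of 1675 bound and 6.94% of 12270 unbound genes (odds ratio 2.63, Fisher's exact test, BH p = 2.27e-32 over 18 motifs). Motif 7 (29.7% against 23.7%, exact BH p = 9.09e-07) and the Motif 5 E-box (20.5% against 15.4%, BH p = 9.09e-07) were also more frequent. So were the consensus sequences of the downstream promoter element DPE (14.99% against 11.0%, exact BH p = 1.68e-05) and the TCT initiator (42.2% against 37.2%, BH p = 2.61e-04). Matches were counted on either strand anywhere in the window. A match to DPE, TCT or the TATA box, here and at summits, is therefore not shown to be a core promoter element in its place. The TATA box (9.37% against 12.1%, exact BH p = 0.00206), the Pho sequence GCCAT (56.3% against 62.6%, BH p = 4.08e-06) and the BEAF-32 core (56.1% against 59.4%, BH p = 0.0247) were less frequent. The Ibf sequence also passed (28.4% against 31.2%, exact BH p = 0.0447), but not without replicate 1, 2 or 3 (BH p = 0.0993, 0.123 and 0.0763), where its log2 odds ratio of -0.19 changed little (-0.18, -0.17 and -0.19). With unbound genes matched on GC content, the BEAF-32 core no longer passed but its log2 odds ratio changed little (-0.16 after -0.19, exact BH p = 0.0751), while that of Ibf fell to -0.017 (BH p = 1). Su(Hw) did not pass (1.43% against 0.929%, exact BH p = 0.115) but did without replicate 1 or 2 (BH p = 0.0318 and 0.0338).

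At the summits themselves 9 of 18 motifs differed from the flank. GAGA factor sites occurred at 6.74% of summits and 4.91% of flanks (BH p = 2.62e-04, exact McNemar test), Motif 7 at 8.11% and 6.07% (BH p = 2.62e-04) and DPE at 4.93% and 3.52% (BH p = 0.00148). The Pho sequence was rarer at summits, 27.5% against 31.5% (exact BH p = 1.19e-04). At promoter peaks alone GAGA factor, Motif 7 and DPE passed (exact BH p = 8.22e-07, 2.69e-09 and 7.36e-05), and outside promoters they did not (BH p = 0.378, 1 and 0.524). BEAF-32 core and the Motif 5 E-box also passed at promoter peaks and not outside them. The same held for Motif 1 and the initiator (exact McNemar test, BH p = 2.64e-07 for the initiator at promoter peaks), which had not passed over all peaks. At a promoter peak the flank, centred 500 bp away, can lie outside the promoter. Sequences frequent at promoters in general could then pass, so this comparison does not tie them to bound promoters. Against unbound promoters, Motif 1 and the initiator did not differ (Fisher's exact test, BH p = 0.655 and 0.642), and BEAF-32 core was less frequent. Within 50 bp of the summit GAGA factor and Motif 7 did not pass (exact BH p = 0.225 and 0.116), and in the stronger 2700 peaks Pho did not (0.157). The palindrome TATCGATA of DREF was found at 1.07% of summits and 0.537% of flanks (log2 ratio 1.05, exact BH p = 0.00579). It did not pass without replicate 3 (0.93, exact BH p = 0.0607), within 50 bp (0.86, BH p = 0.116) or in the stronger 2700 peaks (0.82, BH p = 0.203), where the log2 ratio changed little, nor against non-IDR peaks, where it was 0.47 (BH p = 0.0615). BEAF-32 core (24.1% against 21.8%), Motif 5 (5.30% against 3.93%) and Su(Hw) (0.759% against 0.370%) were more frequent at summits than in flanks and TCT less frequent (21.4% against 23.4%). At promoter peaks alone TCT did not differ from the flank at the threshold (log2 ratio 0.05, exact BH p = 0.843), and its deficit lay outside promoters (-0.26, BH p = 0.0143). With a replicate left out and fewer peaks tested, these 4 motifs kept their direction but missed the threshold: BEAF-32 core and Su(Hw) without any of the replicates (exact BH p up to 0.130 and 0.210), and Motif 5 and TCT without replicate 1 (BH p = 0.0673 for both) or replicate 3 (BH p = 0.199 and 0.0861). There the log2 ratio of TCT hardly changed (-0.17 and -0.16 after -0.17), BEAF-32 core had 0.14 to 0.18 after 0.19, Su(Hw) 0.72 to 1.05 after 1.07, and Motif 5 had 0.34 and 0.25 after 0.45. The Zelda sequence CAGGTAG, which marks early embryonic enhancers, was equally frequent at summits and flanks, at 1.06%.

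An unbiased search gave 11 8-mers enriched in held-out peaks. The palindrome AACATGTT lay within 100 bp of 3.15% of 2700 held-out summits and 0.630% of their flanks (exact McNemar test, BH p = 5.21e-11 over 20 8-mers). The 166 IDR peaks that hold it had a median rank of 704.5 of 5400. The overlapping 8-mers ACATGTTG (3.11% and 1.11%, exact BH p = 1.26e-06) and CATGTTGC (2.63% and 1.33%, BH p = 0.00235) also passed. A second group, CACTGTGC (3.67% and 1.00%, exact BH p = 2.16e-10) and CACAGTGG (3.56% and 1.07%, BH p = 3.29e-09), had median ranks of 2490 and 2454.5. Others share the core CGAAC, with CGAACCGA at 2.33% and 0.667% (exact BH p = 2.08e-06) and ACTCGAAC at 1.78% and 0.481% (BH p = 1.71e-05). Of 121 peaks with CGAACCGA, 41.3% were at promoters. The other 4 were A/T-rich or held AGCAAACA (exact BH p from 0.0116 to 0.0303). In the replicates' strongest peaks AACATGTT was found at 3.08% ± 0.190 of summits and 0.728% ± 0.123 of flanks (SD, n = 3). Without replicate 3, 7 8-mers passed, and 5 of these were among the 11. AACATGTT, ACATGTTG, CACAGTGG and CACTGTGC were called whichever replicate was left out, though CACTGTGC was not in the stronger 2700 peaks. CATGTTGC was not called without replicate 1, ACTCGAAC not without replicate 3, CGAACCGA not without replicate 1 or 3, and the A/T-rich 8-mers and AGCAAACA not when any replicate was left out.

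The 8-mers differed in where they lay. AACATGTT peaked over the summit, with 14.4 copies per 1000 peaks in the central 50 bp, and CACAGTGG lay beside it, with 5.56 in the centre and 11.5 and 13.1 in the bins 100 bp to either side.

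**Figure D3:**
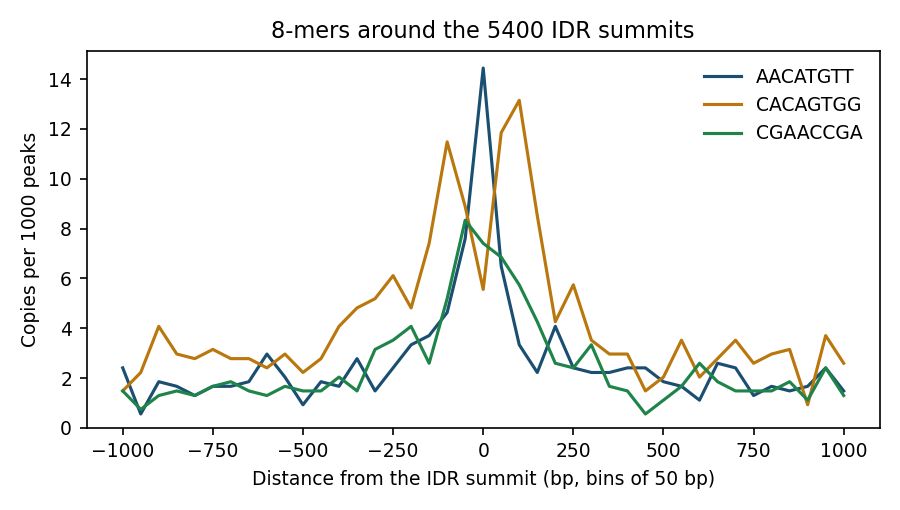
Copies of 3 8-mers per 1000 IDR peaks (vertical axis) in bins of 50 bp by distance from the summit (horizontal axis, bp). AACATGTT reaches 14.4 at the summit, while CACAGTGG falls to 5.56 there and reaches 13.1 at 100 bp.

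IDR peaks clustered around the tagged gene. CG5180 (FBgn0043457, 3R, 20557930 to 20559760, plus strand) had an IDR summit 78 bp from its TSS. Within 50 kb of the gene lay 16 IDR peaks, more than around 97.1% of protein-coding genes, whose median was 5, and within 20 kb lay 13, more than around 99.4%. No more were added within 100 kb, where 16 exceeds the count around 81.0% of genes. The replicates' strongest 5400 peaks gave 16, 16 and 12 within 50 kb, more than around 97.2%, 97.0% and 91.0% of protein-coding genes. The pooled list gave 36 there, more than around 76.1%. Some of the 16 IDR peaks overlap each other, so they are not all separate regions. The best of these peaks ranked 566 with a signal value of 1076, in a 5' UTR at 3R, 20550600 to 20550870. The 3 strongest lay not in CG5180 but in its neighbours Stat92E and DPCoAC, named after their values were seen. When each replicate was left out, 9 or 10 peaks stayed within 50 kb, in a list reduced to between 4029 and 4152 peaks.

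**Figure D4:**
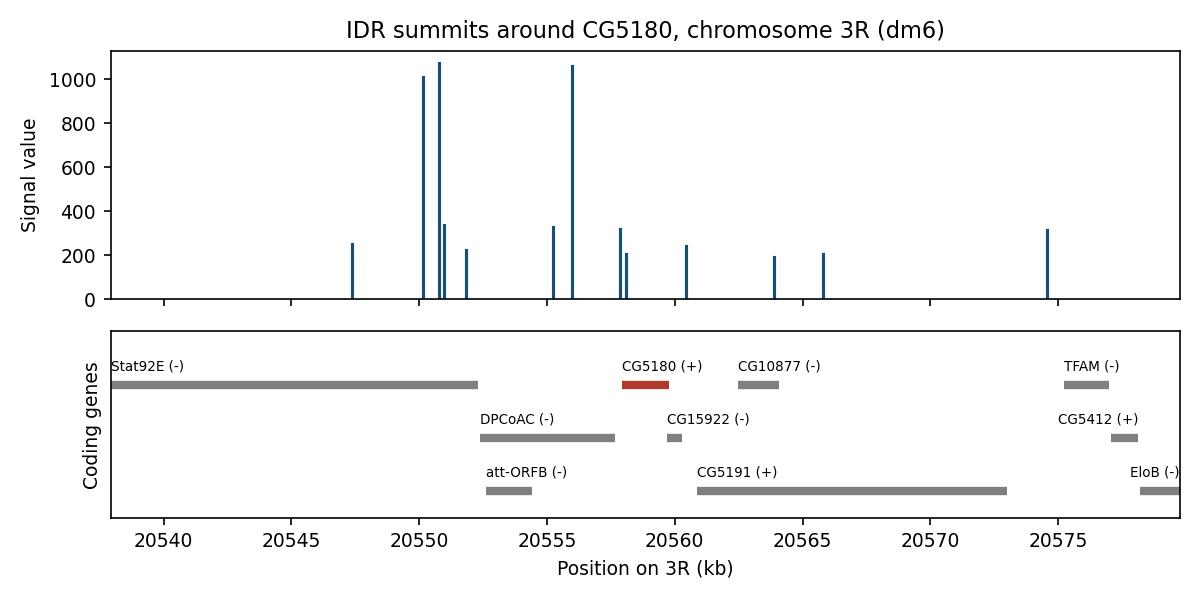
IDR summits within 20 kb of CG5180 on 3R, with signal value on the vertical axis of the upper panel and position in kb on the shared horizontal axis; the lower panel shows protein-coding genes with their strand, CG5180 in red. The 13 summits include 1 at 1076, the highest.

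Each arm's share of IDR peaks lay near its share of non-IDR peaks, and chromosome 4 held few of either. Chromosome 4 had 11.1 IDR peaks per Mb against 37.3 on 3R to 44.1 on 2L, and with protein-coding TSSs as background its odds ratio was 0.375 (Fisher's exact test, BH p = 3.68e-04). The share of IDR peaks on 2L was 19.2% against 21.0% of non-IDR peaks (Fisher's exact test, BH p = 0.0213 over 6 arms), and the replicates gave 19.3% ± 0.205 (SD, n = 3). Arms 2R (18.8% and 17.8%, exact BH p = 0.159), 3L (21.7% and 22.1%, BH p = 0.857) and 3R (22.2% and 20.8%, BH p = 0.0901) did not differ at the threshold. The X held 17.9% and 18.1% (exact BH p = 0.886), and chromosome 4 held 15 IDR peaks (0.278% against 0.288%, BH p = 1). Without replicate 1 or 3 the arm 2L did not pass (exact BH p = 0.145 and 0.203), though its odds ratio of 0.895 changed little (0.908 and 0.913), and with protein-coding TSSs as background its odds ratio was 1.02, while 2R (0.898), 3L (1.16) and 3R (0.921) then passed (BH p = 0.0127, 3.68e-04 and 0.0394).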

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

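Chosen after the data were seen were the background matched on the number of TSSs, the use of only the strongest of overlapping peaks, and all alternatives for 8-mers. The promoter excess of IDR peaks passed under all 11 alternatives, the 5 calls on genomic features under all 6 and that on cytosolic ribosomal proteins under all 12. Of 279 values for features, arms, lists and motifs that had passed, 214 stayed past the threshold in the same direction, 61 fell short of it and 4 changed direction. Of 396 values for those that had not passed, 23 passed in the same direction, among them the proneural and Notch list in other windows and Ibf and Motif 1 at summits. The planned replacement of the IDR list by the strongest peaks of the pooled list gave identical peaks and is not counted. With only genes that have a pooled peak as background, the odds ratio was infinite for chorion genes and gut serine proteases and histones had no member, so no value is given. The cause of each change below was not tested unless stated, and unknown read depth leaves open how many weaker sites were missed.

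Mean recovery of IDR peaks was 81.5% with summits within 100 bp, 99.1% in whole lists and 99.2% for the stronger 2700 peaks. The number of arms past the threshold was 0 for the stronger 2700 peaks and for peaks shared by the 3 replicates, 0 to 1 without a replicate and 4 against coding TSSs. Against those TSSs, odds ratios were 1.02 for 2L, 0.898 for 2R, 1.16 for 3L, 0.921 for 3R, 0.375 for chromosome 4 and 1.06 for X, of which 2R, 3L, 3R and 4 passed. The number of gene lists was 2 with genes that have a pooled peak as background and 5 with TSS number matched. The number of motifs at summits was 4 within 50 bp, 4 at peaks outside promoters, 3 for the stronger 2700 peaks and 4 to 7 without a replicate, where fewer peaks were tested. The number of 8-mers was 7 to 14 without a replicate, and peaks near CG5180 numbered 9 to 10.

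The remaining changes of direction are in results that had not passed, except DRE, BEAF-32 core and the TCT initiator at summits, and none of these values passed. For odds ratios without a replicate the ranges were 0.966 to 1.01 for 5' UTRs, 1.17 to 1.28 for chromosome 4, 0.596 to 1.31 for aminoacyl-tRNA synthetases, 0.826 to 1.29 for the spliceosome, 0.841 to 3.17 for gap genes, 0.998 to 1.58 for muscle genes, 0.596 to 0.948 for cell cycle genes and 0.748 to 1.18 for small nuclear RNAs. With peaks shared by the 3 replicates, odds ratios were 0.964 for 5' UTRs, 1.31 for chromosome 4, 0.665 for aminoacyl-tRNA synthetases and for cell cycle genes, 1.03 for translation initiation factors, 0.896 for the spliceosome and 0.937 for gap genes. With the stronger 2700 peaks they were 1.42 for chromosome 4, 1.01 for X, 0.829 for aminoacyl-tRNA synthetases and for cell cycle genes, 0.535 for the spliceosome, 0 for gap genes, 0.677 for autophagy genes and 1.04 for small nuclear RNAs. With the strongest of overlapping peaks they were 0.971 for 5' UTRs, 1.003 for X and 0.764 for aminoacyl-tRNA synthetases. Within 100 bp they were 0.445 for aminoacyl-tRNA synthetases, 0 for the spliceosome, 0.713 for muscle genes, 0.920 for cell cycle genes, 0.395 for heat shock genes and 1.16 for small nuclear RNAs, and within 1000 bp 1.01 for translation initiation factors and 0.862 for the spliceosome. With the peak interval over the TSS they were 0.841 for cell cycle genes and 1.04 for small nuclear RNAs. With a pooled peak required they were 1.08 for translation initiation factors, 1.35 for general transcription genes, 0.809 for gap genes and 0.539 for cell cycle genes. With TSS number matched, observed over expected was 1.13 for mitochondrial ribosomal proteins, 0.912 for muscle genes, 0.888 for cell cycle genes and 1.498 for small nuclear RNAs.

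For motifs at summits, log2 ratios outside promoters were -1 for DRE, -0.0069 for BEAF-32 core, -0.65 for Motif 1 and -0.12 for the initiator. At promoters they were 0.052 for TCT, -0.28 for CTCF and -0.12 for Ibf. Against non-IDR peaks CTCF had -0.16. CACGTG had 0.17 in the stronger 2700 peaks and 0.13 to 0.25 without a replicate. At bound promoters log2 odds ratios were -0.59 for Su(Hw) and 0.22 for AP-1 within 100 bp, 0.32 for Zelda and 0.0014 for AP-1 in the stronger 2700 peaks, and without a replicate 0.15 to 0.26 for Zelda and -0.13 to 0.017 for AP-1.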

Other observations

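The 5 gene lists of the next paragraph and their tests were chosen after the strongest peaks had been seen, the tests were changed again after their first values (first leaving out the genes of the 25 strongest peaks, then matching the number of TSSs), and GTTCGA was noticed in the sequences of all IDR peaks before the tests on it, of which those without IDR peaks that hold it, their bound at the tagged gene and the ranking of all hexamers in odd-numbered peaks were chosen after the other values had been seen.

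Components of the EGF and FGF receptor pathways were often bound. Of 25 genes of these pathways 14 had an IDR summit at a TSS, among them Egfr, the ligand genes Krn, vn, bnl, pyr and ths, the FGF receptor genes btl and htl, and the ETS factor genes pnt and aop. Without Egfr, pyr and rho, which had drawn attention to the pathway, 11 of 22 were bound. The odds ratio was 7.47 (Fisher's exact test, BH p = 6.44e-05 over 5 lists). In place of Fisher's exact test, random draws matched on the number of TSSs gave 3.75 expected bound genes, against 11 found (BH p = 0.00500). A general excess of these genes among the targets is a hypothesis from the same data, and rho, pyr and ths also belong to the dorsoventral list. None of the 5 lists was set against only the genes with a pooled peak at a TSS. With that background the dorsoventral list had not passed (odds ratio 1.35, Fisher's exact BH p = 0.941). Ecdysone response genes had 7 of 14 bound, EcR, Eip75B, Eip78C, Hr4 and ftz-f1 among them, with an odds ratio of 6.38 without vri (Fisher's exact BH p = 0.00566), but random draws matched on the number of TSSs gave 4.10 where 6 were bound (BH p = 0.644). Planar cell polarity (odds ratio 3.31, exact BH p = 0.0979), integrin and basement membrane (1.65, BH p = 0.382) and axon guidance genes (1.86, BH p = 0.358) did not pass.

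Some genes held many IDR peaks within their bodies. The most were 27 in the 34.7 kb of tara and 25 in the 69.8 kb of Tlk, which encodes a chromatin-associated kinase. Next came kirre (22 in 394 kb), CG1677 and shn (18 each), lilli (17), and Eip75B, bun, mam and ush (16 each). These genes were chosen after their values were seen, and no test was made of their counts.

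The strongest IDR peaks most often held the hexamer GTTCGA, which overlaps the CGAAC core of the 8-mers. It lay within 100 bp of 40.6% of the strongest 540 summits, 15.6% of the next 540 and between 7.59% and 16.3% in each later group of 540, against 8.15% in the flanks of the strongest, and the replicates' strongest 540 peaks gave 40.4% ± 0.566 (SD, n = 3). In 2700 even-numbered peaks the number of copies correlated with signal at Spearman's rho 0.20 (permutation p = 1.00e-05, the smallest that 100000 permutations can give), across peaks that are not replicates. GTTCGA also ranked 1 of 2080 hexamers in odd-numbered peaks alone (rho 0.16). Base composition is argued against by 59 others with the same letters and 1 CpG, of which 0 (0%) correlated as strongly in even-numbered peaks (bootstrap 95% interval of the difference from the highest 0.0382 to 0.125). Promoters as the whole cause are argued against by a rho of 0.15 among 1892 even-numbered peaks outside them (permutation p = 1.00e-05). Among 808 even-numbered promoter peaks rho was higher, at 0.28. Genes for tRNAs, whose internal promoter holds GTTCGA, lay within 250 bp of 0 of the 219 peaks with it in the strongest 540 (0%, upper limit 1.37%). Whether CG5180 recognises this sequence stays open, and a binding assay with the protein and ChIP-seq from another GFP line, not analysed here, would decide it.

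Whether the excess of ribosomal protein promoters comes from high transcription is open, and no transcript levels were analysed here. Of 30 other abundant housekeeping genes 13 were bound (43.3%, Wilson 95% interval 27.4 to 60.8). This was less often than ribosomal protein genes (Fisher's exact p = 0.0319) but more often than other coding genes at 11.6% (p = 1.25e-05). The 13 were the translation factor genes eEF1alpha1, eEF1gamma, eEF2 and eIF4A, and 14-3-3zeta, Eno, Gapdh2, Hsp83, Rack1, Tctp, Ubi-p63E, alphaTub84B and chic. The set is thus not free of translation genes, and it was not tested without them. A lower share than that of ribosomal protein genes had been set as evidence against transcription. That bound did not allow for a graded relation, which the comparison with other coding genes leaves open. Of the broadly expressed lists named next, none passed above other genes. Odds ratios were 0.251 for oxidative phosphorylation, the only one of these to pass, 0.155 for proteasome, 0.630 for general transcription and Mediator, 0.732 for translation initiation factor and 0.776 for mitochondrial ribosomal protein genes. They were 1.01 for aminoacyl-tRNA synthetase, 1.40 for spliceosome and 1.42 for heat shock and chaperone genes. GTTCGA as the whole cause is argued against: without IDR peaks that hold it, 50 ribosomal protein genes stayed bound, an odds ratio of 12.6 (Fisher's exact p = 6.63e-28), and it lay at 12.1% of 58 ribosomal protein promoter peaks and 10.3% of their flanks (exact McNemar p = 1). High transcription and a part played by GTTCGA at some of these promoters (19.7% of 1618 other promoter peaks held it, Fisher's exact p = 0.177) stay open, and the single group gives no biological contrast to test.

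The cluster of IDR peaks at the tagged gene may reflect extra copies of the locus carried by the transgene. Extra copies would raise weak peaks there too, and the pooled list had 25 peaks within 20 kb, more than around 92.1% of coding genes, where the 95th percentile is 28 and the 99th is 44. The exact Poisson interval of 16.2 to 36.9 spans the first of these, so the count neither shows nor excludes extra copies. GTTCGA was held by 2 of the 13 IDR peaks (Fisher's exact p = 1 against other IDR peaks), and the 11 others are still more than around 99.2% of coding genes, with an exact Poisson interval of 5.49 to 19.7 above the median of 1 though not above the 95th percentile of 6, which argues against GTTCGA as the whole cause of the cluster. Extra copies, and binding of the protein at its own locus by other means, stay open.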
